A study of Mus musculus with 3 samples.

How the data were processed

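Skin ILCs of wild-type C57Bl/6 mice aged 8 weeks were profiled with the 10x Genomics Chromium 3' kit (v2), in 1 library each from epidermis, dermis and subcutis. The deposited matrices hold raw UMI counts per gene and cell barcode, as integers with no normalization, from filtered gene-barcode matrices, 1 per library. Per the submitters' processing notes, Cell Ranger 2.2.0, Seurat 2.3.4 and the mm10 build were used, with no role or order given for each tool. The matrices list 27998 genes by identifier and symbol and 9298 barcodes in all. The number of mice per library, the sort and any antibody gate are not stated. Gene positions came from the GENCODE M21 annotation, in which 386 of 386 identifiers looked up were matched.

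Barcodes with under 500 detected genes (0 epidermal, 10 dermal and 16 subcutaneous) or over 10% mitochondrial UMIs (91, 32 and 10) were removed. Doublets were scored with Scrublet in scanpy, and the automatic threshold marked 15 barcodes (0.16%), of which 1 was epidermal, 2 were dermal and 12 subcutaneous. Over all libraries this was read as not having worked, although the subcutaneous number equals the one removed below. The barcodes with the highest scores were removed instead, up to an expected rate of 0.8% per 1000 barcodes, which took out 133, 127 and 12. This fallback was chosen after the data were seen. The cells that passed numbered 3848, 3822 and 1200. Counts were scaled to 10000 per cell and log transformed, 2000 variable genes were scaled, and 30 principal components and 15 neighbours gave a shared-neighbour graph that was clustered with Leiden at resolution 1.0, all libraries together and without batch integration.

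Clusters were named from 25 marker lists fixed before the data were examined, as were the filters, the comparisons, 22 gene lists, 24 genes for shares of cells, 7 gene pairs, the rule for named genes and 13 alternative settings. The scoring rule was set after the data were seen: a name needed at least 3 markers found in at least 10% of a cluster's cells at 2-fold or more over the other cells, and at least 1 marker among the cluster's 10 top genes. Top genes were ranked by fold of mean CPM with a pseudocount of 1 CPM among genes found in at least 25% of the cluster's cells. T cell markers took precedence over ILC markers. Cluster 12 carried T cell and ILC3 markers together (Cd3e, Il23r and Il1r1 among its top genes), so T cell-like cells are compared between layers by cluster number. Cells in clusters not named as another cell type, unnamed clusters included, are ILC-classed: 3493, 3640 and 1185 cells. ILC-classed cells were clustered again with the same settings as a description.

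Raw counts were summed over the ILC-classed cells of each library and divided by the summed total to give CPM with exact Poisson intervals. Ratios between libraries carry exact binomial (Clopper-Pearson) intervals, and shares of cells carry exact binomial ones. These 95% intervals cover counting error only and not variation between mice or preparations. Those of CPM and of ratios treat every UMI as independent and so also leave out variation between cells. A library with 0 counts was set to 3 counts, which makes the ratio a bound. A list member was measured if it reached 10 CPM in the higher library of a pair and was counted as higher when it differed at least 2-fold. The 22 lists held 362 gene symbols, of which 347 are symbols in the files. Those that are not are the T cell receptor constant and variable genes, Il26ra and the aliases Cd103, Znf683 and Hobit, whose genes are in the files and lists as Itgae and Zfp683, and of the marker lists also the immunoglobulin genes and Igj. Each list's median log2 ratio was set beside 10000 random lists of the same size matched on mean expression in 20 bins, as a description and not as a test. Genes were also named by a rule over all genes, list members included: the 12 per direction and pair with the highest lower bound of the ratio at 25 CPM or more in the higher library, without ribosomal, mitochondrial, predicted and clone-named genes and markers of non-lymphoid cells, which are reported together. Reads of near-identical genes (Hspa1a and Hspa1b, Apol9a and Apol9b, Il22 and Iltifb, Bcl2a1b and Bcl2a1d) cannot be assigned with certainty.

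For shares of cells with a UMI, every cell was thinned at random to 2400 UMIs, the 20th percentile of the library where it is lowest, rounded down, and shallower cells were left out. Alternatives changed the cell filter (none, or 1000 genes and 5% mitochondrial UMIs), the cells (all that passed), the doublets (kept in), the scaling (mean over cells, median-of-ratios, totals without ribosomal and mitochondrial genes, cells thinned), the floor (5 or 50 CPM), the clustering (resolution 0.5 or 2.0, or each library on its own) and the thinning depth (1200 UMIs). After the data were seen, 2 settings were added: ILC-classed cells without clusters that had at least 2 immediate-early or heat shock genes among their 10 top genes (clusters 3, 8 and 10, of which cluster 10 was also led by Gimap genes), and without the ILC3-like, ILC1- or NK-like and cycling clusters.

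The calculation was checked on counts simulated from the libraries with 200 genes changed per pair. The simulated counts were Poisson draws from 1 pooled profile per pair, which is the model the intervals assume. They hold no variation between cells, so they check the calculation and not the coverage in these data. The intervals held the true ratio for 95.6%, 95.0% and 95.4% of unchanged genes in the pairs epidermis with subcutis, epidermis with dermis and dermis with subcutis, and 4-fold changes were called in 100% of cases in each pair. Of 100 random lists per pair, 4, 3 and 6 lay outside the central 95%. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9, with random seed 1.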

Results

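Innate lymphoid cells (ILCs) are lymphocytes without rearranged antigen receptors, and their group 1, group 2 and group 3 forms are told apart by transcription factors and cytokines. Droplet-based single-cell RNA sequencing measured the transcriptomes of ILCs from the epidermis, the dermis and the subcutis of the skin of wild-type C57Bl/6 mice aged 8 weeks. Each layer is represented by 1 library, so there were 3 libraries and no replicates. The epidermal library held 4072 cell barcodes with 17519209 unique molecular identifiers (UMIs, counted RNA molecules) and a median of 4237 UMIs per barcode. The dermal library held 3990 barcodes, 13971529 UMIs and a median of 3415.5, and the subcutaneous library held 1236 barcodes, 5186541 UMIs and a median of 4215.5. The design asks how the ILCs of the 3 layers differ in the genes they express. With 1 library per layer, layer and library cannot be told apart, no test across samples was possible, and no p-value is given. All intervals in parentheses are exact 95% intervals that cover counting error only.

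Most cells of each library fell in clusters that were named ILC-like or cycling, or that the marker rule did not name, and these are called ILC-classed cells. They made up 90.8% (89.8 to 91.7) of 3848 epidermal cells that passed the filters, 95.2% (94.5 to 95.9) of 3822 dermal cells and 98.8% (97.9 to 99.3) of 1200 subcutaneous cells. Of the ILC-classed cells, 3416 of 3493 in epidermis, 3561 of 3640 in dermis and 219 of 1185 in subcutis were in clusters that no marker list named, and the ILC2-like cells numbered 0, 25 and 903. That the unnamed cells are ILCs rests on the labels of the libraries, whose sort is not described, so these percentages are shares of cells in clusters not named as another type. Of 17 clusters, cluster 4 (928 cells, 97.3% of them subcutaneous) was ILC2-like by its marker genes, and its top genes included Il1rl1, Arg1, Klrg1 and Pparg. Clusters 1, 5, 7 and 11 were epidermal and were led by genes such as Cx3cr1, Tff1, Nkg7 and Iigp1. The dermal clusters 2, 3, 6, 8 and 14 were led by genes such as Crem, Atf3, Hey1 and Hspa1a, and cluster 10 was subcutaneous and led by Gimap3, Hspa1b and Klf2. These clusters stayed unnamed by the marker rule. Smaller clusters were ILC3-like (cluster 15; Il22, Cd4 and Igfbp7 among its top genes), ILC1- or NK-like (cluster 16; Gzmc and Xcl1) and cycling (cluster 13). Clusters 9 and 12 were T cell-like and cluster 17 was keratinocyte-like, and these 3 clusters were left out of the ILC-classed cells. Cluster 12 also carried ILC3 markers, with Il23r and Il1r1 beside Cd3e among its 10 top genes, and its name rests on the precedence of T cell markers, a rule set after the data were seen. A cluster that comes mostly from 1 library may reflect that library and not a cell type, so cluster sizes are not compared between layers. The comparisons of layers use UMIs summed over the ILC-classed cells of each library, given as counts per 1000000 UMIs (CPM). The sums were 14642843 UMIs in epidermis, 12520284 in dermis and 5013668 in subcutis. Summed counts also depend on which cells a library holds. A ratio between layers, such as that of a group 2 gene, therefore mixes the make-up of cells with the level per cell.

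The comparison of epidermis with subcutis asks how the outermost and the deepest layer differ. Most measured genes of group 2 ILCs were higher in the subcutis library. Il5, a cytokine that drives eosinophils, reached 4537 CPM in subcutis and 46.3 CPM in epidermis, a ratio of 98.0-fold (90.8 to 106). Il1rl1, which encodes the receptor for the alarmin IL-33, was 879.6-fold higher in subcutis (491 to 1764), and the inhibitory receptor gene Klrg1 was 877-fold higher (461 to 1920.3). Arg1, the gene of the arginine-degrading enzyme arginase 1, was 191-fold higher in subcutis (144 to 259). Gata3, the transcription factor on which group 2 ILCs depend, reached 2222 CPM in subcutis and 463 CPM in epidermis, a ratio of 4.80-fold (4.65 to 4.94). Other genes were higher in the epidermis library, among them Ccr6, the receptor for the chemokine CCL20, at 22.2-fold (19.0 to 26.1), and Itgae, the integrin chain that binds E-cadherin, at 85.2-fold (61.8 to 121).

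Of 270 measured members of the 22 fixed gene lists, 88 were at least 2-fold higher in the epidermis library and 101 were at least 2-fold higher in the subcutis library. The ratios are scaled to total UMIs, and the median log2 ratio of all 7685 measured genes, epidermis over subcutis, was 0.63. Scaling by median-of-ratios shifts every log2 ratio by -0.58, and 56 members were then at least 2-fold higher in epidermis and 132 in subcutis. List medians are therefore given relative to the median of all genes. The 2-fold counts of list members, here and for the other pairs, are not corrected in this way. They lean toward the layer on whose side that median lies, and the share of all genes that differ 2-fold was not counted. In the group 2 list, 12 of 18 measured members were higher in subcutis and 5 in epidermis, and the list median lay at -3.34 relative to all genes, below all of 10000 random lists. Il13 was 2.17-fold higher in subcutis (2.11 to 2.23), Csf2 16.6-fold (15.5 to 17.7), Calca 18.4-fold (16.8 to 20.1) and Areg 8.95-fold (8.49 to 9.45). Members higher in epidermis included Il17rb, the receptor for IL-25, at 9.33-fold (6.56 to 13.7) and Il4 at 4.64-fold (3.09 to 7.28).

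In the group 3 list, 8 of 14 members were higher in subcutis and 4 in epidermis, with a median of -1.68 relative to all genes (percentile 0.02 of random lists). Ccr6 was on the epidermal side, whereas Il22, a cytokine gene that acts on epithelial cells, was 42.0-fold higher in subcutis (36.9 to 48.0), although its reads are hard to tell from those of the near-identical gene Iltifb. The 63 ILC3-like cells of the subcutis library gave 85.9% of its Il22 UMIs. Without the ILC3-like, ILC1- or NK-like and cycling clusters, a choice made after seeing the data, the log2 ratio of epidermis over subcutis was -2.95 for Il22 in place of -5.39. It was then 6.31 for Ccr6 in place of 4.47, 5.37 for Lta in place of 3.70, and 0.53 for the median of the group 3 list in place of -1.05. In the group 1 and NK list, 4 of 7 members were higher in subcutis and 3 in epidermis (-2.35 relative to all genes, percentile 0.06). Klrk1 was 9.94-fold higher in epidermis (7.41 to 13.7) and Ccl5 42.3-fold higher in subcutis (29.7 to 62.2), while Tbx21, the group 1 transcription factor, stayed under 5 CPM in all 3 libraries. At a floor of 50 CPM the uncorrected median of this list turned from -1.73 to 0.41.

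Of 9 circulation and naive state members, 6 were higher in subcutis and 1 in epidermis, and the median of -4.76 relative to all genes lay below all random lists. Klf2, a transcription factor that promotes lymphocyte recirculation, was 17.6-fold higher in subcutis (15.9 to 19.5), Klf3 47.7-fold (35.8 to 64.8) and Satb1 41.6-fold (33.3 to 52.5). In the residency and adhesion list 7 of 15 members were higher in epidermis and 3 in subcutis (0.05 relative to all genes, percentile 89.0), with Cdh1, the E-cadherin gene, at 84.1-fold (23.1 to 696) on 2 subcutaneous UMIs. Among 11 chemokine receptors 6 were higher in subcutis and 3 in epidermis (-2.83, below all random lists). Ccr2 was 66.6-fold higher in subcutis (56.1 to 79.7), and Cx3cr1, the receptor for fractalkine, was 294-fold higher in epidermis (81.2 to 2426) on 2 subcutaneous UMIs. The uncorrected chemokine receptor median of -2.20 became -0.51 at a floor of 50 CPM and -0.63 without the ILC3-like, ILC1- or NK-like and cycling clusters.

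Of 25 secreted cytokines and chemokines, 16 were higher in subcutis and 5 in epidermis (-3.35 relative to all genes, below all random lists), and the neutrophil chemokine gene Cxcl2 was 33.7-fold higher in subcutis (31.2 to 36.5). Il2 was 5.76-fold higher in epidermis (4.88 to 6.83). The TNF superfamily ligands went the other way, with 6 of 10 higher in epidermis and 2 in subcutis (0.63 relative to all genes, percentile 99.3). The lymphotoxin genes Lta and Ltb were 13.0-fold (9.85 to 17.4) and 4.43-fold (4.21 to 4.67) higher in epidermis, and Cd70 was 26.2-fold higher (18.2 to 39.2). Among 20 cytokine and alarmin receptors 8 were higher in epidermis and 7 in subcutis (-0.27, percentile 40.7), with Il1r2 54.4-fold higher in epidermis (35.5 to 88.04) and Il2ra 8.06-fold higher in subcutis (7.44 to 8.74). Il7r, the IL-7 receptor chain used to define ILCs, was 1.23-fold higher in epidermis (1.17 to 1.30), a direction that turns under median-of-ratios scaling. Of 15 co-stimulatory and inhibitory receptors 5 were higher in epidermis and 6 in subcutis (-1.33, percentile 0.18), with Cd83 33.5-fold higher in epidermis (24.0 to 48.1) and Pdcd1, the gene of PD-1, 31.5-fold higher in subcutis (26.1 to 38.2).

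Metabolic and stress lists are summarised in the same way. In the lipid handling list 7 of 18 members were higher in subcutis and 5 in epidermis (-1.15 relative to all genes, percentile 0.05). Alox5, the gene of 5-lipoxygenase, was 392-fold higher in subcutis (152 to 1444), the nuclear receptor gene Pparg 219.6-fold (93.3 to 680.3) and Dgat1, which encodes an enzyme of triglyceride synthesis, 30.1-fold (27.7 to 32.8). Glycolysis and hypoxia genes were higher in epidermis in 9 of 20 cases and in subcutis in 1 (0.16, percentile 96.8), with Bnip3 at 10.9-fold (7.28 to 17.1) and Tpi1 at 4.95-fold (4.51 to 5.43). Cell cycle genes were higher in epidermis in 12 of 16 cases (1.39, percentile 99.99), and the other 4 lay within 2-fold. The cycling cluster held 57 epidermal and 0 subcutaneous cells. Without the ILC3-like, ILC1- or NK-like and cycling clusters the uncorrected cell cycle median was 1.005 in place of 2.013. Heat shock genes were higher in subcutis in 7 of 11 cases (-2.04, percentile 0.05), immediate-early genes in 8 of 21 with 3 higher in epidermis (-1.49, below all random lists), and NF-κB response genes in 6 of 14 with 2 higher in epidermis (-1.57, percentile 0.14). Interferon response genes were higher in subcutis in 6 of 12 cases and in epidermis in 3 (-1.64, percentile 0.03), with Isg15 11.9-fold higher in subcutis (10.49 to 13.6).

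Of 15 ILC identity members 5 were higher in epidermis and 4 in subcutis (-0.68 relative to all genes, percentile 18.6). The counts were 3 and 3 of 10 for the Notch pathway (-0.37, percentile 13.4), 4 and 3 of 11 for the TGF-β response (-0.49, percentile 17.3), 2 and 0 of 4 for MHC class II (0.84, percentile 92.1) and 2 and 1 of 4 for the T cell receptor complex (0.25, percentile 75.1). In the TGF-β list Smad7 was 7.09-fold higher in epidermis (5.81 to 8.75). Under median-of-ratios scaling the uncorrected medians of the cytokine receptor, Notch and TGF-β lists change sign, and that of the Notch list also does so at a floor of 50 CPM (-0.35 in place of 0.25). The largest moves of other uncorrected medians by more than 1.5 times were to -4.05 from -2.72 for secreted factors, to -1.31 from -0.53 for lipid handling, to 0.90 from 2.01 for the cell cycle, to 0.82 from 1.46 for MHC class II and to 1.71 from 0.88 for the T cell receptor complex.

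**Figure D1:**
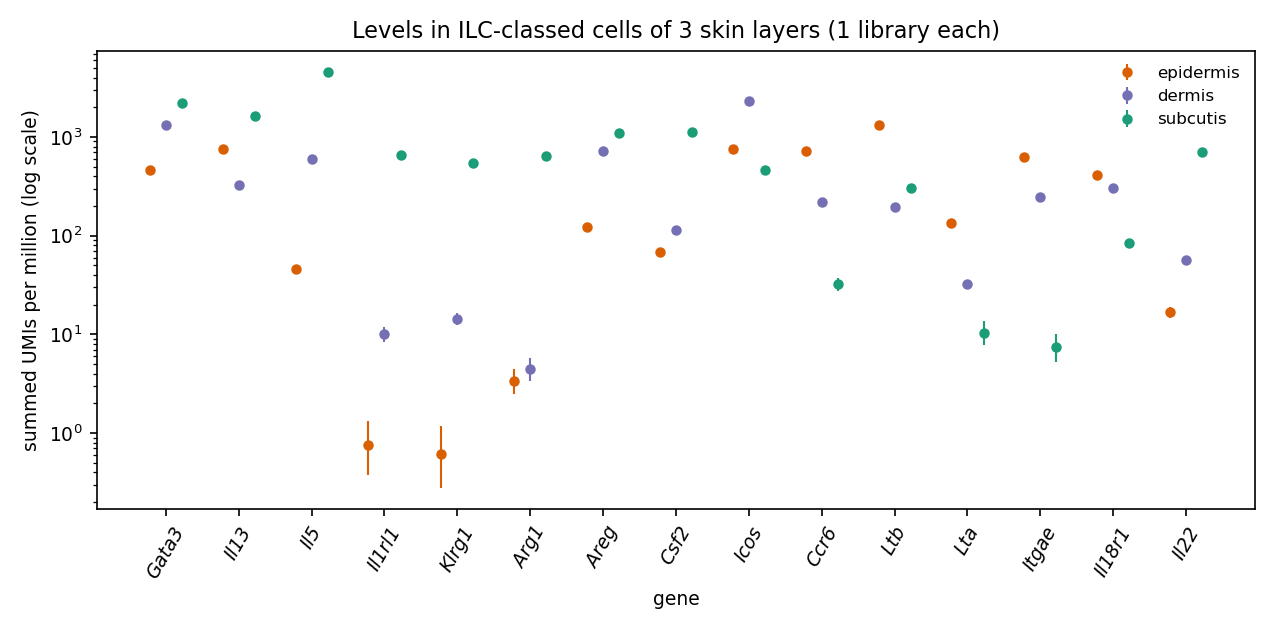
Summed UMIs per 1000000 (CPM) in ILC-classed cells (vertical logarithmic axis) for 15 genes (horizontal axis), 1 point per library of epidermis, dermis and subcutis, with exact Poisson 95% intervals as error bars. Il5, Il1rl1, Klrg1 and Arg1 are highest in the subcutis library, and Ccr6, Ltb, Lta and Itgae are highest in the epidermis library.

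The rule for named genes took, from all genes and with list members included, the 12 genes per direction with the highest lower bounds of the ratio. On the epidermal side these were Cx3cr1, Itgae, Apol9a, Apol9b, Rnf208, Tff1, Ncmap, Ly6g5b, Ctsw, Asic3, Susd2 and Sardh. Apol9b and Apol9a, near-identical genes whose reads are hard to assign, had no subcutaneous UMI. By the lower ends of their exact intervals they were at least 133.95-fold and at least 86.8-fold higher in epidermis. Tff1, a trefoil factor gene, was 229-fold higher (98.2 to 707) and Ctsw, the gene of the protease cathepsin W, was 75.8-fold higher (56.9 to 103). On the subcutaneous side they included Il1rl1, Klrg1, Arg1, Il6, Alox5, Gimap3, Gimap4, Gimap6, Rab27b, Plac8 and Cd24a. Gimap3 and Gimap6, which encode GTPases of lymphocyte survival, were 455-fold (229.96 to 1055) and 239-fold (154 to 392) higher in subcutis. Plac8, with no epidermal UMI, was at least 149.76-fold higher in subcutis by the lower end of its exact interval. Several of these folds rest on few UMIs in the lower library. With cells thinned to 1 depth the log2 ratio was 5.20 for Sardh in place of 7.80, 5.85 for Ncmap in place of 8.40, 4.77 for Asic3 in place of 6.07 and -6.97 for Il6 in place of -9.78. Asic3 had no subcutaneous UMI, so both its values are bounds set by the 3 counts put in for 0. Sardh and Ncmap had 1 subcutaneous UMI each and Il6 had 1 epidermal UMI. Where thinning lost that UMI, the thinned value is such a bound and not a measured ratio. The log2 ratio was -11.03 for Il1rl1 in place of -9.78 without clusters 3, 8 and 10, which carry stress genes among their top genes, and -10.80 for Gimap3 in place of -8.83 without the ILC3-like, ILC1- or NK-like and cycling clusters.

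Several of the genes that differ lie close together in the genome (mm10, GENCODE M21 coordinates). Il5 (ENSMUSG00000036117) spans 53720794 to 53725106 on chromosome 11, and Il13 (ENSMUSG00000020383) spans 53631324 to 53634702 on the same chromosome. Ltb (ENSMUSG00000024399) and Lta (ENSMUSG00000024402) lie on chromosome 17 at 35194439 to 35196320 and 35203165 to 35205351. The genes Gimap4 (48684549 to 48692060), Gimap6 (48701582 to 48708225), Gimap5 (48746197 to 48754210) and Gimap3 (48764464 to 48770851) all lie on chromosome 6. Gata3 (ENSMUSG00000015619) lies on chromosome 2 at 9857078 to 9890034 and Il1rl1 (ENSMUSG00000026069) on chromosome 1 at 40429570 to 40465415. All of these are annotated as protein-coding genes.

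The comparison of epidermis with dermis asks how the ILCs of adjacent layers differ. Of the 12 genes named on each side, Ramp3, Crem and Plaur were higher in the dermis library and Ramp1 and Ltb in the epidermis library. Ramp3, a partner of the calcitonin receptor-like receptor, reached 1241 CPM in dermis and 13.5 CPM in epidermis, a ratio of 91.7-fold (79.7 to 106), whereas Ramp1, another partner of that receptor, was 6.41-fold higher in epidermis (6.04 to 6.80). Crem, a cyclic AMP-responsive transcription factor gene, was 34.1-fold higher in dermis (31.9 to 36.4), and Plaur, the urokinase receptor gene, was 80.8-fold higher (55.0 to 124). Il5 was 12.9-fold higher in dermis (11.9 to 14.0) and Gata3 2.87-fold higher (2.79 to 2.95). Ltb and Lta were 6.76-fold (6.49 to 7.06) and 4.19-fold (3.76 to 4.68) higher in epidermis.

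Of 253 measured list members, 42 were at least 2-fold higher in the epidermis library and 92 in the dermis library. Under median-of-ratios scaling, which shifts every log2 ratio by -0.36, the counts were 24 and 113, and the median log2 ratio of all 7646 measured genes was 0.42. The group 2 list held 9 of 16 members higher in dermis and 2 in epidermis (-2.00 relative to all genes, below all random lists), with Calca at 7.78-fold (7.12 to 8.51), Areg at 5.93-fold (5.64 to 6.25) and Rora, a transcription factor of ILC2 development, at 3.88-fold (3.78 to 3.97). Il13 ran the other way at 2.32-fold higher in epidermis (2.24 to 2.40), which falls under 2-fold with median-of-ratios scaling (log2 0.85). The group 3 list held 5 of 12 members higher in epidermis and 1 in dermis (0.44, percentile 98.4). Ccr6 was 3.30-fold (3.17 to 3.45) higher in epidermis, and Il22 was 3.42-fold higher in dermis (2.96 to 3.97), or -0.54 on the log2 scale in place of -1.78 without the ILC3-like, ILC1- or NK-like and cycling clusters. Of the dermal Il22 UMIs, 65.55% came from 7 ILC3-like cells, so the interval is too narrow for the sampling of cells. Of 6 group 1 and NK members 4 were higher in dermis and 1 in epidermis (-2.05, percentile 0.11). Gzmb, the granzyme B gene, was 254-fold higher in dermis (69.8 to 2102) on 2 epidermal UMIs, and Xcl1 was 5.42-fold higher in epidermis (4.41 to 6.72), with 87.7% of the epidermal Xcl1 UMIs from 19 ILC1- or NK-like cells.

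Immediate-early genes were higher in dermis in 13 of 21 cases and in epidermis in 1 (-1.59 relative to all genes, below all random lists), led by Ier3 at 31.8-fold (20.4 to 52.5), Atf3 at 16.9-fold (15.4 to 18.6) and Nr4a2 at 11.0-fold (9.71 to 12.4). Heat shock genes were higher in dermis in 6 of 12 cases and in epidermis in 0 (-1.61, percentile 0.02), with Hspa1a, hard to tell from its copy Hspa1b, at 22.1-fold (20.3 to 24.1). Clusters 3, 8 and 10, with 6 epidermal, 1434 dermal and 201 subcutaneous cells, each had at least 2 immediate-early or heat shock genes among the 10 top genes. Cluster 10, with 200 of these subcutaneous cells, was led by Gimap genes and Klf2 as well as Hspa1b and Dnajb1, so leaving it out also removes those genes' cells. Without these clusters, a choice made after seeing the data, 51 list members were at least 2-fold higher in epidermis and 80 in dermis, the uncorrected immediate-early median was -0.24 in place of -1.16, that of heat shock genes was -0.82 in place of -1.18, and the log2 ratio of Hspa1a was -2.45 in place of -4.47. NF-κB response genes were higher in dermis in 7 of 14 cases and in epidermis in 0 (-1.37, percentile 0.15), with Rel at 4.74-fold (4.48 to 5.02). Co-stimulatory and inhibitory receptors were higher in dermis in 10 of 15 cases and in epidermis in 2 (-2.05, below all random lists). Cd28 was 12.5-fold (9.82 to 16.2) and Icos, a co-stimulatory receptor of ILC2s and T cells, 3.08-fold (3.01 to 3.15) higher in dermis.

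Of 22 secreted factors 9 were higher in dermis and 2 in epidermis (-1.16, below all random lists), of 9 chemokine receptors 5 and 2 (-1.66, percentile 0.17), and of 7 circulation genes 5 and 0 (-2.41, percentile 0.01). Ccr2 was 7.78-fold (6.49 to 9.39) and Satb1 17.1-fold (13.7 to 21.6) higher in dermis, while Cx3cr1 was 3.93-fold higher in epidermis (3.51 to 4.41). Besides the group 3 list, 4 lists held more members higher in epidermis than in dermis. These were residency and adhesion with 5 and 3 of 15 (0.04, percentile 75.4), interferon response with 3 and 1 of 10 (0.18, percentile 73.3), cell cycle with 7 and 1 of 16 (0.53, percentile 98.3) and the T cell receptor complex with 1 and 0 of 3 (0.56, percentile 94.4). Itgae was 2.53-fold higher in epidermis (2.43 to 2.64), and Isg15 was 12.01-fold higher in dermis (10.7 to 13.6). The uncorrected cell cycle median of 0.95 became -0.43 without the ILC3-like, ILC1- or NK-like and cycling clusters, -0.29 at a floor of 50 CPM and 0.11 as a mean over cells, and the chemokine receptor median of -1.24 became -0.24 at a floor of 50 CPM. Lipid handling genes were higher in epidermis in 4 of 15 cases and in dermis in 5 (-0.18, percentile 30.3), with Dgat1 19.9-fold (18.3 to 21.6) and Hilpda, a lipid droplet gene, 9.82-fold (9.19 to 10.51) higher in dermis, and Scd2 5.29-fold higher in epidermis (4.32 to 6.54).

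ILC identity genes were higher in dermis in 5 of 14 cases and in epidermis in 0 (-0.89, percentile 1.57), with Nfil3, a transcription factor gene of early ILC development, 3.99-fold higher in dermis (3.72 to 4.29). The counts for epidermis and dermis were 3 and 6 of 19 for cytokine and alarmin receptors (-0.40, percentile 17.6), 3 and 3 of 10 for TNF superfamily ligands (-0.32, percentile 25.8), 2 and 2 of 10 for the Notch pathway (-0.28, percentile 18.8) and 2 and 4 of 11 for the TGF-β response (-0.38, percentile 22.6). They were 1 and 2 of 5 for MHC class II (-0.94, percentile 3.24) and 1 and 3 of 19 for glycolysis and hypoxia (-0.41, percentile 22.5). Ifngr1, which encodes a chain of the interferon-γ receptor, was 5.31-fold higher in dermis (5.08 to 5.55), and Tgfbr1, which encodes a TGF-β receptor chain, was 4.38-fold higher in epidermis (4.01 to 4.80). The Notch target genes Hes1 and Hey1 were 21.8-fold (14.9 to 33.2) and 12.7-fold (9.65 to 17.0) higher in dermis. Under median-of-ratios scaling the uncorrected medians of the cytokine receptor, TNF ligand, Notch, TGF-β, lipid handling and glycolysis lists change sign, as does the 1.02-fold ratio of Il7r, and the lipid handling median also does so at a floor of 50 CPM (-0.50 in place of 0.24).

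The remaining named genes on the epidermal side were Apol9a, at 72.8-fold (40.5 to 146), Apol9b, at 37.4-fold (26.5 to 54.6), Cysrt1, Ly6g5b, Rnf208, Asic3, Sardh, P2ry1, Prr29 and Fam83a. Ly6g5b reached 537 CPM in epidermis and was 10.6-fold higher there (9.80 to 11.5). On the dermal side they included Gzmb, Cpm, AW011738, Cystm1, Igsf5, Ier3, Hspa1a and Plagl1, with Igsf5 at 30.7-fold (23.9 to 40.1). With all cells that passed the filters in place of ILC-classed cells the log2 ratio of Gzmb was -7.06 in place of -7.99, and without clusters 3, 8 and 10 that of Apol9b was 6.05 in place of 5.23.

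The comparison of dermis with subcutis completes the 3 pairs. Several group 2 genes were again higher in the subcutis library, with Il5 at 7.61-fold (7.41 to 7.81), Il13 at 5.02-fold (4.84 to 5.22), Il1rl1 at 65.7-fold (55.0 to 79.1), Klrg1 at 37.5-fold (32.2 to 43.9) and Arg1 at 143-fold (109.98 to 189.99). Gata3 was 1.67-fold higher in subcutis (1.63 to 1.71). Icos ran the other way, at 2317 CPM in dermis and 468 CPM in subcutis, or 4.95-fold higher in dermis (4.75 to 5.16). Itgae was 33.7-fold (24.4 to 47.9), Klrk1, the gene of the activating receptor NKG2D, 26.0-fold (19.4 to 35.6) and Cd83 33.8-fold (24.2 to 48.6) higher in dermis.

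Of 263 measured list members, 67 were at least 2-fold higher in the dermis library and 60 in the subcutis library. Under median-of-ratios scaling, which shifts every log2 ratio by -0.22, the counts were 55 and 67, and the median log2 ratio of all 6867 measured genes was 0.20. In the group 2 list 9 of 18 members were higher in subcutis and 5 in dermis (-1.19 relative to all genes, below all random lists). In the group 3 list 7 of 14 were higher in subcutis and 2 in dermis (-1.39, below all random lists), with Il22 at 12.3-fold (11.3 to 13.3) and Tmem176b at 11.6-fold (10.9 to 12.4). Ccr6 was 6.71-fold higher in dermis (5.73 to 7.92). Without the ILC3-like, ILC1- or NK-like and cycling clusters the uncorrected group 3 median turned from -1.19 to 0.09 and the log2 ratio of Il23r from -2.47 to 0.43. Those of Ccr6, Lta and Il22 were then 4.57, 2.94 and -2.41 in place of 2.75, 1.63 and -3.62. Group 1 and NK members were split 2 and 2 of 6 (0.35, percentile 94.1).

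Secreted factors were higher in subcutis in 13 of 25 cases and in dermis in 5 (-1.44, below all random lists), circulation genes in 6 of 9 with 1 higher in dermis (-1.61, below all random lists) and chemokine receptors in 5 of 11 with 3 higher in dermis (-0.25, percentile 14.1). Csf2, the gene of GM-CSF, was 9.78-fold (9.23 to 10.4), Klf3 12.1-fold (10.2 to 14.3) and Ccr2 8.56-fold (7.95 to 9.23) higher in subcutis. Lipid handling genes were higher in subcutis in 5 of 16 cases and in dermis in 2 (-0.78, below all random lists), with Alox5 at 670.5-fold (185 to 5551) on 2 dermal UMIs and Pparg at 24.1-fold (17.3 to 34.4). Interferon response genes were higher in subcutis in 5 of 12 cases and in dermis in 1 (-0.46, percentile 0.84). The lists on the dermal side were TNF superfamily ligands with 5 of 10 higher in dermis and 1 in subcutis (0.57, percentile 99.7), residency and adhesion with 4 and 3 of 14 (0.42, percentile 99.9), and glycolysis and hypoxia with 5 and 1 of 20 (0.50, percentile 99.99). Cell cycle genes were higher in dermis in 5 of 9 cases (0.97, above all random lists), MHC class II in 4 of 5 (1.02, percentile 99.6) and TGF-β response genes in 5 of 11 with 1 higher in subcutis (0.42, percentile 99.3). Cd70 was 16.6-fold (11.5 to 24.95), Tnfsf9, the gene of 4-1BB ligand, 7.70-fold (6.34 to 9.44), Cd74 4.74-fold (4.38 to 5.14) and Smad7 8.36-fold (6.85 to 10.3) higher in dermis. The dermal ILC-classed cells include 16 dendritic or Langerhans cell-like cells with Cd74 and MHC class II genes among their top genes. Their part in these ratios was not tested.

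Immediate-early genes were higher in dermis in 4 of 21 cases and in subcutis in 1 (0.39, percentile 99.97), and without clusters 3, 8 and 10 their uncorrected median was -0.17 in place of 0.59. All 12 heat shock genes lay within 2-fold (-0.38, percentile 6.87). NF-κB response genes were higher in dermis in 3 of 14 cases and in subcutis in 1 (-0.08, percentile 64.6), and the counts for dermis and subcutis were 4 and 2 of 15 for ILC identity (0.08, percentile 85.7), with Tox, a transcription factor gene of ILC development, at 5.21-fold (4.67 to 5.82). They were 5 and 3 of 20 for cytokine and alarmin receptors (0.15, percentile 94.7), 6 and 4 of 15 for co-stimulatory and inhibitory receptors (-0.30, percentile 9.68), 3 and 2 of 11 for the Notch pathway (-0.46, percentile 0.98) and 1 and 1 of 4 for the T cell receptor complex (-0.39, percentile 12.5). Tnfrsf4, the gene of OX40, was 15.1-fold (12.6 to 18.3) and Hey1 20.3-fold (11.5 to 39.5) higher in dermis, and Notch2 was 3.48-fold higher in subcutis (3.03 to 3.998). The NF-κB median turns under median-of-ratios scaling, and those of the chemokine receptor and co-stimulatory lists turn with cells thinned to 1 depth. The remaining named genes were Tff1, Cx3cr1, Amica1, Hopx, Nsg2, Ctsw, Il1r2, Sox4 and Pde4a on the dermal side and Gimap3, Gimap4, Gimap5, Gimap6, Gda, Plac8, Igfbp4, Igfbp7 and Tspan13 on the subcutaneous side. Gimap3 was 183-fold (114 to 315), Gimap6 86.9-fold (65.0 to 119) and Tspan13 45.6-fold (38.6 to 54.1) higher in subcutis. Gda, with no dermal UMI, was at least 87.4-fold higher in subcutis by the lower end of its exact interval. Hopx, a homeodomain-only protein gene, was 21.9-fold (16.4 to 29.97) and Amica1, an adhesion molecule gene, 21.7-fold (17.7 to 27.0) higher in dermis, and without the ILC3-like, ILC1- or NK-like and cycling clusters the log2 ratio of Amica1 was 5.49 in place of 4.44. The uncorrected median of the T cell receptor complex list turned from -0.19 to 0.58 in all cells that passed the filters.

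Across the layers, 189 list genes were at least 2-fold apart between epidermis and subcutis. The dermis library lay between the other libraries for 135 of them (71.4%), highest for 37 and lowest for 17. Gata3, at 463, 1330 and 2222 CPM in epidermis, dermis and subcutis, Il5, at 46.3, 596 and 4537 CPM, and Ccr6, at 716, 217 and 32.3 CPM, were among the genes with dermis in between. Tnfrsf4, Cd44 and Atf3 were highest in the dermis library, and Il13, Ltb and Tmem176b were lowest there.

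**Figure D2:**
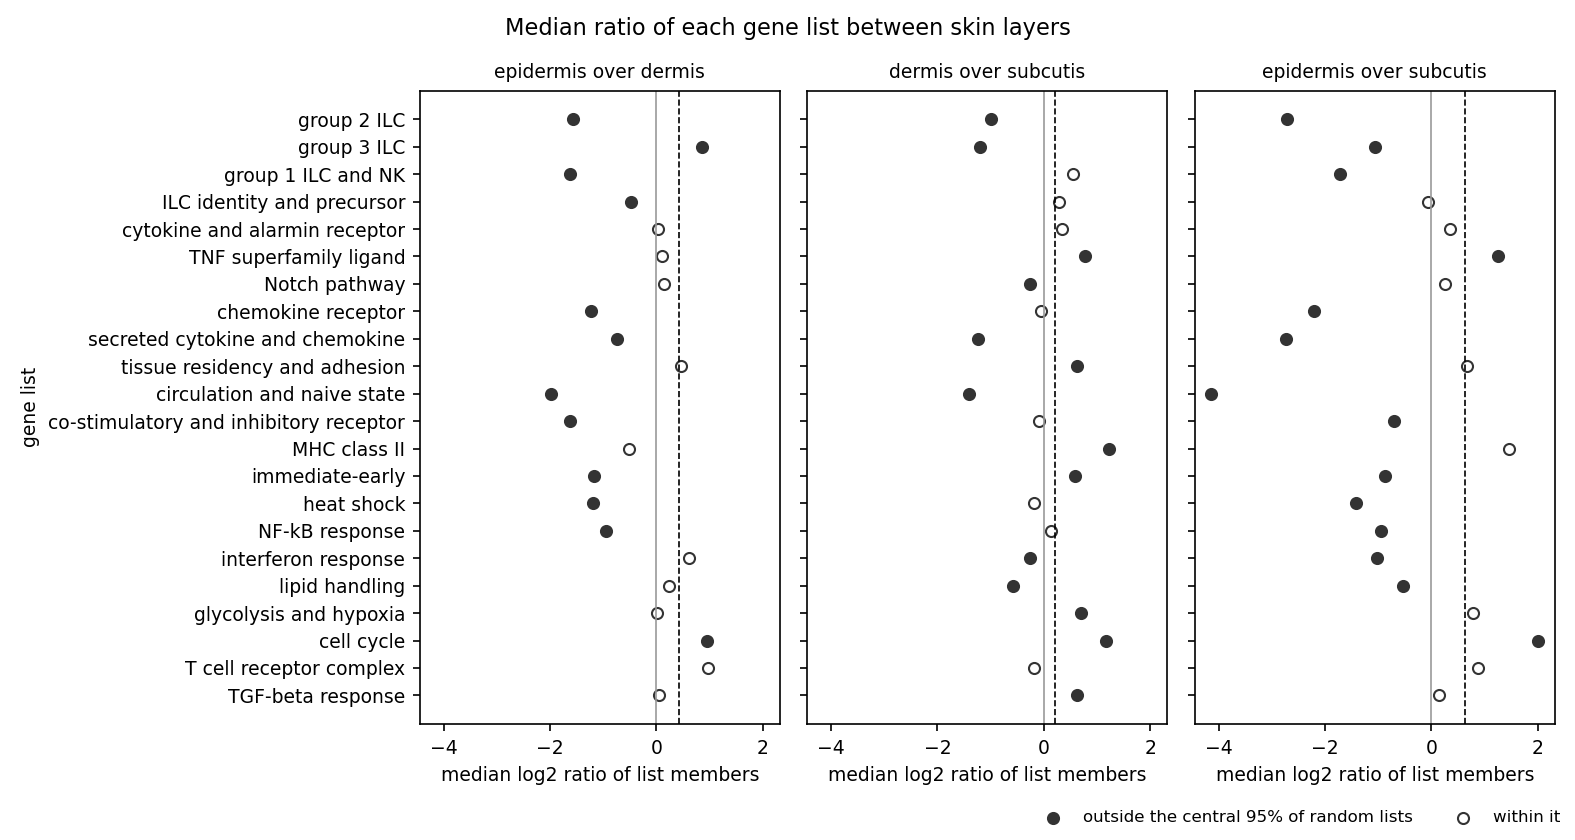
Median log2 ratio (horizontal axis) of the measured members of each of 22 gene lists (vertical axis), with panels for epidermis over dermis, dermis over subcutis and epidermis over subcutis; the solid line marks 0 and the dashed line the median of all genes. Filled points lie outside the central 95% of random lists matched on expression and open points within it, and the circulation, group 2 and secreted factor lists lie left of the dashed line in all 3 panels.

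Shares of cells with at least 1 UMI were compared after each cell was thinned to 2400 UMIs, which left out 462 epidermal, 697 dermal and 158 subcutaneous cells. Il5 was found in 9.44% (8.42 to 10.53) of 3031 epidermal cells, 43.5% (41.7 to 45.3) of 2943 dermal cells and 94.2% (92.5 to 95.5) of 1027 subcutaneous cells; the unthinned shares were 15.4%, 47.8% and 97.1%. Before thinning the ILC-classed cells had a median of 4162, 3375 and 4245 UMIs. T cell-like cells, which were taken as the class to lack Il5 after the data were seen, had Il5 in 6.89% of 334 thinned epidermal cells and 12.4% of 169 thinned dermal cells, with median depths of 5313 and 4271 UMIs. The epidermal Il5 share is close to that background and the dermal one is above it. In the subcutis library 53 thinned ILC3-like cells, with a median depth of 6246 UMIs, had Il5 in 88.7% (77.0 to 95.7), so the subcutaneous share is not read as the share of cells that express Il5. The 22 thinned keratinocyte-like cells of all libraries together, with a median depth of 4642 UMIs, had Il5 in 27.3% (10.7 to 50.2), Il13 in 40.9% (20.7 to 63.6) and Ccr6 in 36.4% (17.2 to 59.3). These wide intervals hold the dermal shares of all 3 genes and the epidermal share of Il13. Il1rl1 was found in 0.13%, 1.33% and 72.6% (69.8 to 75.3) of the thinned ILC-classed cells of epidermis, dermis and subcutis, in 0% of the epidermal T cell-like cells and in 22.6% (12.3 to 36.2) of the subcutaneous ILC3-like cells. Its unthinned shares were 0.17%, 1.76% and 83.6%. Gata3 was found in 61.1%, 82.6% and 91.8% of the thinned cells (75.5%, 85.9% and 95.8% unthinned), and in 38.0% and 27.2% of the epidermal and dermal T cell-like cells. Il13 was found in 61.6%, 31.5% and 70.8% (73.3%, 37.4% and 82.5% unthinned), against 48.2% and 8.28% of the T cell-like cells, and 55.7% of the epidermal Il13 UMIs came from the 868 epidermal cells of cluster 5.

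Ccr6 was found in 75.6% (74.0 to 77.1), 33.0% and 4.28% of the thinned cells of epidermis, dermis and subcutis (86.5%, 41.0% and 6.33% unthinned). Among T cell-like cells it was found in 71.9% (66.7 to 76.6) of epidermal and 24.3% (18.0 to 31.4) of dermal thinned cells, so the epidermal share is close to theirs. It was found in 1.26% of 795 thinned subcutaneous ILC2-like cells with a median depth of 4280 UMIs. Il17a was found in 0.40% of epidermal, 0.61% of dermal and 0 of 1027 subcutaneous thinned cells, which allows a share of up to 0.29% of cells with a UMI. Detection of gene pairs in the same thinned cell was compared with the product of the single shares. Il13 and Il5 were found together in 186 epidermal cells where 176 would follow from the product, a ratio of 1.06 (0.91 to 1.22), in 418 dermal cells where 404 would follow and in 696 subcutaneous cells where 685 would follow.

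**Figure D3:**
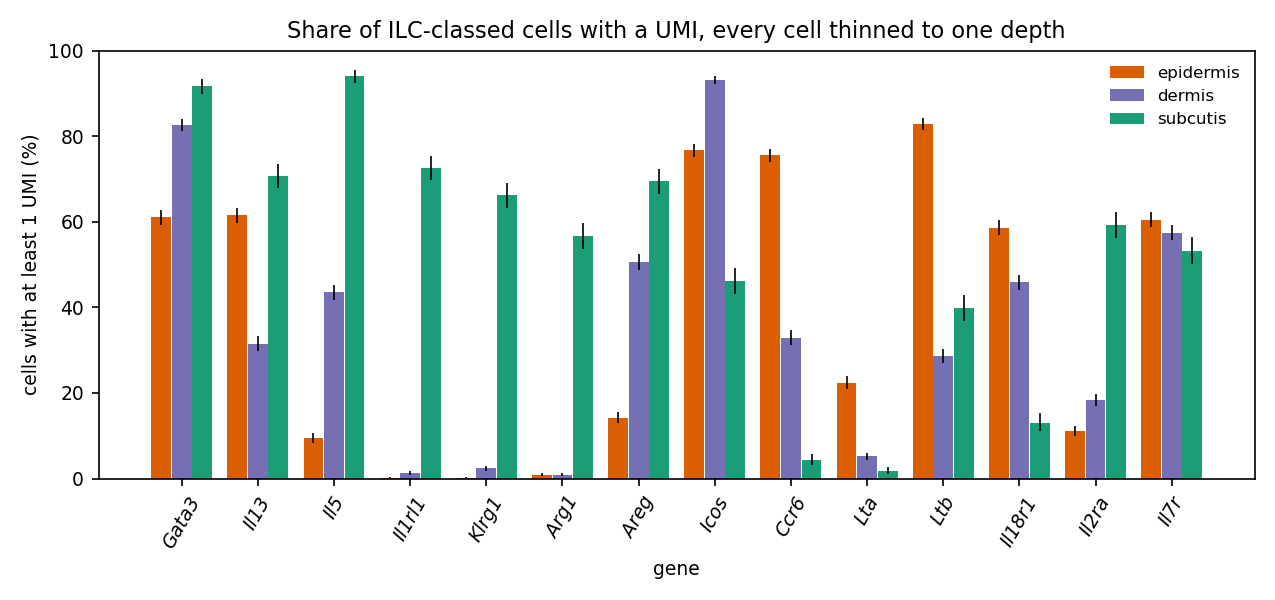
Percentage of ILC-classed cells with at least 1 UMI after thinning to 2400 UMIs (vertical axis, from 0) for 14 genes (horizontal axis), with bars for epidermis, dermis and subcutis and exact binomial 95% intervals as error bars. The Il5 bars stand at 9.44%, 43.5% and 94.2%, and the Ccr6 bars at 75.6%, 33.0% and 4.28%.

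Markers of non-lymphoid cells were low in the ILC-classed cells, with the median of each marker class at 15.5 CPM or less. The highest single markers were Cd74 at 546, 632 and 133 CPM in epidermis, dermis and subcutis, Ccr2 at 9.29, 72.3 and 619 CPM, the keratinocyte marker Sfn at 91.7, 364 and 225 CPM, and the haemoglobin gene Hba-a1 at 47.6, 107 and 213 CPM. Lymphocytes also express Cd74 and Ccr2. Reclustering of the ILC-classed cells gave 15 clusters, among them 1 of 17 cells, 16 of them dermal, that was led by Ccr7, H2-Aa, H2-Ab1, H2-Eb1 and Cd74 and was named dendritic or Langerhans cell-like. These cells are among the ILC-classed cells of the comparisons, and their part in the MHC class II results was not tested. Of the T cell markers, Cd3e lay at 4.58 CPM in the epidermal and 1.60 CPM in the dermal ILC-classed cells, Cd3g at 463 and 247 CPM, and Lat at 356 and 181 CPM.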

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

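The counts in this part are descriptive, and the explanations of what the T cell-like cells show are weighed under the other observations, with tests chosen after the result was seen.

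Cells with markers of another type than ILC appeared in libraries labelled as ILC, and the comparisons of ILC-classed cells left them out. They enter the setting with all cells that passed the filters, and T cell-like clusters 9 and 12 are compared under the other observations. T cell-like cells, in clusters 9 and 12 with Cd3e and Cd163l1 among their top genes, numbered 341 in the epidermis library (8.86% of cells that passed the filters), 176 in the dermis library (4.61%) and 10 in the subcutis library (0.83%). Keratinocyte-like cells, in cluster 17 with Krtdap and Krt14 among its top genes, numbered 14 in the epidermis library, 6 in the dermis library and 5 in the subcutis library. They are listed because each count is above 3 cells, the limit that a count of 0 allows. No control library exists, so the counts do not show whether more of these cells are present than a sort would leave. Cluster 9 was mostly epidermal and cluster 12 mostly dermal, so the numbers also depend on where the clusters divide, and they are not compared between layers.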

How the results depend on the processing

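No paired analysis was possible because each layer is a single library, and replicate numbers carry no pairing. Of 120 log2 ratios, of the genes named by rule and of those chosen for shares of cells, 1 that was at least 2-fold turned: Il23r, dermis over subcutis, was 0.43 without the ILC3-like, ILC1- or NK-like and cycling clusters. Under 2-fold, Il7r turned under median-of-ratios scaling, and for epidermis over dermis Il7r and Tnf turned without clusters 3, 8 and 10, Tnf from -0.24 to 1.06. Ratios that no longer reached 2-fold numbered 2 under median-of-ratios scaling, 2 without the ILC3-like, ILC1- or NK-like and cycling clusters, 1 without clusters 3, 8 and 10 and 1 in all cells. Leaving out the ILC3-like, ILC1- or NK-like and cycling clusters also turned the median of the group 3 list to 0.53 for epidermis over subcutis and 0.088 for dermis over subcutis, and the cause was not tested. A floor of 50 CPM turned the group 1 list median for epidermis over subcutis to 0.41 because fewer members were measured. Members at least 2-fold higher in epidermis numbered 56 against subcutis and 24 against dermis under median-of-ratios scaling, which shifts every gene, and 22 against dermis at a floor of 50 CPM, which also left 39 higher in subcutis than dermis, with fewer genes measured. The ILC-classed share was 91.94% in epidermis at Leiden resolution 0.5; with each library clustered on its own it was 91.81% in epidermis, 93.93% in dermis and 100% in subcutis, and under the stricter filter 94.39% in dermis, and the cause was not tested. Log2 ratios moved by more than 1.5 times in 20 of 120 cases with cells thinned, 20 without the ILC3-like, ILC1- or NK-like and cycling clusters, 10 without clusters 3, 8 and 10, 4 in all cells, 3 as a mean over cells and 2 under the stricter filter. Some of these, such as Asic3 with cells thinned, are bounds against a library with 0 counts. Median-of-ratios scaling moved 0 of 120 by more than 1.5 times, although it shifts every log2 ratio. Shares of cells moved in 58 of 69 cases at 1200 UMIs, a count that does not use the limit of 1.5 times. They therefore hold for the depth used. Depth limits genes with few UMIs in the lower library, such as Il6, whose ratio of subcutis over epidermis has an interval of 157 to 34836.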

Other observations

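The tests of explanations in this part were chosen after the results were seen, except the test of cell depth on stress genes, and so was the choice of T cell-like clusters 9 and 12 as a comparison.

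The T cell-like cells differ between layers in ways the report has not described. Cluster 9 supplied 341 epidermal cells with 1860278 UMIs and cluster 12 supplied 166 dermal cells with 731268 UMIs. Both carried Cd3e, at 184 CPM and 325 CPM against 4.58 and 1.60 CPM in the ILC-classed cells of the same libraries, and Cd163l1, a gene of γδ T cells, at 958 and 1216 CPM. Other T cell markers differed less from the ILC-classed cells or were absent. Cd3d lay at 40.9 and 47.9 CPM against 7.10 and 2.40 CPM. Cd3g lay at 1048 and 867 CPM against 463 and 247 CPM, and Lat at 735 and 507 CPM against 356 and 181 CPM. Cd4, Cd8a and Cd5 had 0 UMIs in both clusters, and Cd6 and Cd8b1 had 1 UMI each in the epidermal and 0 in the dermal cluster. Il17f, a cytokine gene of type 17 lymphocytes, reached 299 CPM in the epidermal and 204 CPM in the dermal cluster. Il22 was 10.6-fold (8.56 to 13.2) and Il23r, the IL-23 receptor gene, 4.68-fold (3.21 to 6.92) higher in the dermal cluster, while Il13 was 12.1-fold higher in the epidermal cluster (8.69 to 17.4). Ccr6 and Itgae were 4.03-fold and 2.18-fold higher in the epidermal cluster, as in the ILC-classed cells, where they were 3.30-fold and 2.53-fold higher. The group 2 gene Il5, at 36.6 and 67.0 CPM, did not show the 12.9-fold ratio of the ILC-classed cells, and Gata3 was 1.48-fold higher in the epidermal cluster where the ILC-classed cells had it 2.87-fold higher in dermis. Cluster 12 also carried ILC3 markers and was named by the precedence of T cell markers, so it is not cleanly apart from ILCs. These clusters come almost wholly from 1 library each, so cell type and library are joined in them.

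The ILC3-like cells of the subcutis library, 63 in number, had Il22 at 8365 CPM against 104.85 CPM in the subcutaneous ILC2-like cells. They held 94.8% of the Il17f UMIs and 88.8% of the Il23r UMIs of the subcutaneous ILC-classed cells. Among 53 of them thinned to 2400 UMIs, 88.7% (77.0 to 95.7) had a UMI of Il5 and 22.6% had a UMI of Il1rl1. The median log2 ratio of all genes, epidermis over subcutis, was 0.63 in the comparison, 0.59 without 66 genes that take the most UMIs and 0.59 without 125 ribosomal and mitochondrial genes.

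The median immediate-early or heat shock gene lay on the dermal side in ILC-classed cells, at a gap of -1.59 (log2, epidermis over dermis) to the median of all genes. Thinning every cell to 1 depth left a gap of -1.53 over 33 genes. Random thinning keeps each gene's expected part of a cell's UMIs, so a gap in summed counts would change little either way. This value therefore cannot tell whether the lower number of UMIs per dermal cell plays a part. In the T cell-like clusters the gap was -1.32 over 32 genes, 0.83 of that in ILC-classed cells. This is consistent with handling that differed between the epidermal and dermal libraries, which would act on every cell type in them. The gap of the same genes was -1.56 for epidermis over subcutis and 0.042 for dermis over subcutis, with an upper quartile of 0.60 among the 33 genes. The latter value pools lists that went opposite ways. Relative to all genes, dermis over subcutis, immediate-early genes lay at 0.39 (percentile 99.97) and heat shock genes at -0.38 (percentile 6.87). For heat shock genes this argues against handling of the dermal library alone. For immediate-early genes, which were also higher in dermis than in subcutis, such handling stays open. Handling that set the epidermis library apart from both others stays open, as does a difference between the tissues, which was not tested.

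For 135 list genes the dermis library lay between epidermis and subcutis, and carry-over of cells from the adjacent layers could give such values. Carried-over cells bring all their transcripts, so genes that are low in dermis limit their share. Outside the 135, the lowest gene allows 2.47% of dermal UMIs from epidermal cells and 0.54% from subcutaneous cells, and the 10 lowest genes all lie at or under 16.55% and 2.59%. With the wider shares taken out, 118 of the 135 genes were still in between, under the 90% set as the bound against carry-over, and with the narrower ones 131 were. All 10 epidermal genes behind these limits are among the genes named between epidermis and dermis, most of which also differ in the T cell-like clusters. Their level may follow the library and not the cell, so the limits need not hold for carried-over cells, and carry-over stays open. Only 24 of 3640 dermal ILC-classed cells (0.66%) have a barcode that also occurs in another library, which argues against barcodes read into the wrong library. A graded difference between the layers stays open as a hypothesis, and with 1 library per layer it cannot be separated from differences between preparations.

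Of the 24 genes named between epidermis and dermis, 23 reached 10 CPM in the T cell-like clusters. Of these, 22 differed there at least 2-fold in the same direction. The exception was Ltb, 1.86-fold (1.68 to 2.055) higher in the epidermal cluster against 6.76-fold in ILC-classed cells. Ramp3 was 107-fold (72.9 to 163), Crem 46.3-fold (36.9 to 59.0) and Hspa1a 25.5-fold (19.9 to 33.2) higher in the dermal cluster. Free RNA from ILC-classed cells would leave only a small part of their level in other cells. The median level of the 23 genes in the T cell-like clusters was 88.5% of that in ILC-classed cells. This median does not hold for each gene. Plaur and Igsf5 each lay at 15.04 CPM in the dermal cluster, against 143.45 and 134.34 CPM in dermal ILC-classed cells. For such genes free RNA stays open. Named genes with levels near the median may follow the layer or its library in more than the ILC-classed cells. Cluster 12 carries ILC3 markers too, which limits this reading. Tissue and library preparation both remain open.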
